A study of Mus musculus with 9 samples.

How the data were processed

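The values analysed are the deposited log2 RMA intensities (per the labels and the submitters' processing notes) of the Affymetrix mouse PM array, 45077 probe sets on 9 arrays. Per the submitters' processing notes the arrays were normalized by RMA and handled in Transcriptome Analysis Console 4.0.1.36. Per the labels, frozen bladders were pulverised, RNA was purified with RNeasy columns, and 100 ng was labelled with the GeneChip 3' IVT Express kit. Per the labels the mice were female C57BL/6J. A genome build was not given in the sources used here.

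The 2 experiments were normalized apart. The sorted values of the arrays of an experiment deviated from their mean by 0.022 log2 on average, and those of the 2 experiments differed by 0.329. Before any fit it was therefore decided to use the experiment number given in the labels as a block, although the planned design named none, because separately normalized values are to be compared within an experiment. The planned fit without the block is given beside the counts in the report. Healthy PBS and tumour PBS were the only groups present in both experiments, and the correlation of same-numbered deviations from the group mean was 0.647.

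Probe sets were assigned to genes by the annotation supplied with the array and the gene table: 28898 probe sets named 1 gene, 551 named several, 15588 named none and 40 were control probe sets left out, and 28689 were matched by Entrez number. Of the probe sets of a gene, the one with the highest mean over the arrays was used (7180 genes had more than 1). Genes whose mean lay in the lowest 30% (below 4.16 log2) were left out, which kept 11969 of 17097 genes. Groups with a single array were assumed to vary as much as the replicated groups. The fit left 1 residual degree of freedom in most comparisons, with 2.23 prior degrees of freedom from the variance moderation.

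Differences were fitted with limma (lmFit and eBayes), p-values were moderated t-test values adjusted by Benjamini-Hochberg, and a gene was called at adjusted p under 0.05. The dose slope is in log2 per mM over the sham-treated and treated tumours, and with the block it rests on those of experiment 1. Genes were named by a fixed rule: the 5 largest increases and 5 largest decreases of a comparison among passing genes with every array beyond both controls, up to 4 passing members of each list by size, and 10 genes named throughout, of which Ddx3y was not measured. Where no gene passed, the 5 highest and 5 lowest values and up to 2 members per list were given as values. Gene lists with at least 3 members above the filter (27 lists) were tested with camera at its preset correlation of 0.01, with camera at a correlation estimated from the data, and with fry. Camera at the preset correlation judges a list against the spread between genes, so its p-values do not measure replication between bladders. With an estimated correlation camera uses the residual degrees of freedom, 1 to 3 here, and could hardly call any list. The B and plasma cell, Y-linked and female host lists had too few members above the filter. Lists called "adjusted over the list alone" had Benjamini-Hochberg adjustment over their own members only. The share of linear signal kept is the signal above healthy divided by that of the sham-treated tumour of the same experiment. It was taken over genes at least 4-fold higher in the tumour of the other experiment and at least 2-fold higher in that of the same experiment. The choice of genes therefore also used arrays that form the share. The liver, kidney, glucocorticoid and germline lists were written after the values were seen.

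With 200 of the 11969 genes given an artificial change, a log2 change of 1 was called in 0% in the tumour, 17 mM and 24 h comparisons. A change of 2 was called in 79%, 62% and 45% of the genes, and a change of 4 in 98%, 90% and 94%. Unchanged genes called numbered 10, 9 and 1. In the tumour comparison of the real data 6852 genes were called, and 3482 of them changed at least 2-fold, so smaller changes were called too. At 17 mM genes with changes under 1 also passed, such as Cdkn1a. Where many more than 200 genes change, the adjusted threshold is looser, so the shares above do not carry over to those comparisons.

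The alternatives tried were no block, all arrays quantile-normalized together, another or no expression filter, the mean of probe sets, a variance trend, a 2-fold requirement, other codings of dose, 7 separate group means, and leaving out single arrays. The 4 PBS arrays were left out one at a time where they entered a fit, the dose arrays for the treated arm and the dose slope, and the 24 h array for comparisons that do not use it, while the 7 d array was not left out. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.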

Results

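The series holds 9 mouse bladder arrays from 2 numbered experiments. Per the labels, MB49 cells, a mouse bladder carcinoma line, were put into the bladders of female mice on day 0. Alpha1-oleate, a complex of a peptide with oleate, was given into the bladder 5 times between day 3 and day 11, at 1.7, 8.5 or 17 mM. Sham-treated mice received PBS, and bladders were taken at day 12. Healthy mice received 17 mM alpha1-oleate and were sampled after 24 h or 7 d, with PBS controls. Experiment 1 holds 5 arrays (healthy PBS, tumour PBS and the 3 doses in tumours). Experiment 2 holds 4 (healthy PBS, tumour PBS, and the healthy bladders 24 h and 7 d after 17 mM). Healthy PBS and tumour PBS have 2 arrays each, 1 per experiment. Every other group has 1 array, so the number of arrays limits the precision. The labels do not say whether the arrays come from separate animals, so the p-values measure only the spread between these samples, part of which may be technical. In most comparisons that spread comes from the healthy PBS and tumour PBS arrays alone. Groups with 1 array add none, so their p-values do not measure variation between treated bladders. Median signal ran from 4.42 to 4.45 log2 in experiment 1 and from 4.20 to 4.24 in experiment 2. The expression filter left 11969 genes. The gene lists and main comparisons were fixed before the data were examined, except the liver, kidney, glucocorticoid and germline lists. The tests at 8.5 and 1.7 mM singly, the contrast with the 7 d array alone, the shares of linear signal, the counts of genes above both sham-treated tumour and healthy bladder, and the correlations of the array labelled healthy, 17 mM, 24 h with the tumours were added later.

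Sham-treated tumour bladders held much more transcript of proliferation and inflammation genes, and much less of urothelial and muscle genes, than tumour-free bladders (2 arrays against 2). Top2a, the topoisomerase that untangles replicated DNA, rose by 6.16 (log2 difference, SE 0.09), Birc5, a mitotic survivin, by 6.06 (SE 0.18) and Mki67, a proliferation marker, by 5.88 (SE 0.09). S100a8, a subunit of the neutrophil protein calprotectin, rose by 6.50 (SE 0.17), Mmp13, a collagenase, by 6.14 (SE 0.12), and Prkg2, a cGMP-dependent kinase, by 6.23 (SE 0.11). Upk2, a plaque protein of the urothelial surface, fell by 3.43 (SE 0.09), Upk3b fell by 4.36 (SE 0.18), and Pparg, a regulator of urothelial differentiation, fell by 3.88 (SE 0.17). The largest decreases were in Pcp4, a calmodulin-binding protein (-5.66, SE 0.49), Acaa1b, a peroxisomal thiolase (-5.34, SE 0.39), Uchl1 (-5.08, SE 0.22), Fbp1 (-4.95, SE 0.18) and Cldn8, a tight-junction claudin (-4.89, SE 0.20).

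All 24 tested members of the cell cycle list rose (24 when adjusted over the list alone) with a median log2 difference of 4.06, among them Cep55 (5.78). All 24 of the DNA replication list rose (24 adjusted over the list alone, median 2.42), among them Rrm2, the small subunit of ribonucleotide reductase (5.18). Of the 20 urothelial differentiation genes 19 fell (20 adjusted over the list alone, median -3.33), including Grhl3 (-3.88). The basal and squamous keratinocyte list was split, with 5 of 15 members up and 7 down (6 and 8 adjusted over the list alone). Krt14, a basal keratin, rose by 5.52. Its usual partner Krt5 fell by 3.16 and Trp63, the basal-layer transcription factor, fell by 4.33. All 16 contractile smooth muscle genes fell (16 adjusted over the list alone, median -1.92), from Pgm5 (-2.67), Synpo2 (-2.49) and Lmod1 (-2.35) to Acta2, the smooth muscle actin (-0.98, SE 0.15, adjusted p = 0.014). Of the adipose genes 5 of 5 fell (5 adjusted over the list alone), with Fabp4 at -2.31 and Adipoq at -1.86.

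Leukocyte genes were higher in the tumours. Of the neutrophil list 10 of 11 rose (10 adjusted over the list alone, median 2.48). Of the macrophage list 15 of 17 rose (16, median 2.45), with Arg1, an arginase of activated macrophages, at 4.89 and Cd68 at 3.40. Of the T and NK cell list 10 of 12 rose (10, median 1.30), with Gzmb, a cytotoxic granule protease, at 3.31 (SE 0.35) and Cd3e, a T cell receptor chain, at 0.48 (SE 0.10, adjusted p = 0.0295). Of the dendritic cell and class II list 8 of 11 rose (9 adjusted over the list alone), including H2-DMa (3.04). The B and plasma cell list had only 2 members above the filter and was not tested (Cd79a 4.06 to 4.93 and Cd22 5.96 to 6.71 across the 9 arrays). Of the inflammatory cytokines 14 of 15 rose (15 adjusted over the list alone, median 2.07), with the neutrophil attractant Cxcl2 at 5.94, the monocyte attractant Ccl2 at 5.33 and Il1b at 3.83 (SE 0.41, adjusted p = 0.00737). Of the interferon and antigen presentation list 17 of 19 rose and 1 fell (17 and 1 adjusted over the list alone), with Cxcl9 at 5.98 and Cxcl10 at 5.67.

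Of the 13 invasion proteases 10 rose and 1 fell (10 and 1 adjusted over the list alone), including Adam8 (5.11) and Mmp9 (4.82). Of the 20 hypoxia and glycolysis genes, 19 rose (20 adjusted over the list alone), including the hexokinase Hk2 (3.20), Pgk1 (2.40) and Car9, an acid-base enzyme (2.21). Of the RAS-ERK feedback genes 10 of 15 rose (11 up and 1 down adjusted over the list alone), with Hbegf at 4.70 and the ERK phosphatase Dusp6 at 3.05. Of the heat shock and unfolded protein response genes 13 of 20 rose and 2 fell (13 and 2 adjusted over the list alone). Of the fatty acid oxidation genes 11 of 16 fell and 2 rose (11 and 2), with Pdk4, a brake on glucose oxidation, at -4.62. Of the sterol synthesis genes 9 of 15 fell and 1 rose (10 and 1). The growth factor receptor list moved both ways (7 up and 6 down of 16, the same adjusted over the list alone), with Met at 1.72 and Fgfr2 at -2.29. So did the p53 target list (6 up and 4 down of 14, the same adjusted over the list alone), in which Perp, also a desmosome protein, fell by 3.58. The EMT list did too (6 up and 2 down of 12, the same adjusted over the list alone), and in it S100a4 rose by 4.06 and the epithelial adhesion gene Cdh1 fell by 3.08. Among fibroblast and collagen genes 5 of 18 rose and 3 fell (5 and 3), with Lox at 1.18 and Dpt at -2.32. Col1a1 read 0.54 (SE 0.28, adjusted p = 0.192). Most endothelial genes did not pass (2 up and 3 down of 15, 1 and 3 adjusted over the list alone), nor did most mast cell genes (1 and 1 of 6, 0 and 1). Nerve genes had 1 up and 1 down of 4 (1 and 1). In contrast, 4 of 8 striated muscle genes fell and 1 rose (4 and 1), with Ckm at -2.49, and 3 of the 4 erythroid genes rose (3). Xist, transcribed from the inactive X of female cells and the single gene kept from the female host list, fell by 1.21 (SE 0.09, adjusted p = 0.00404). None of the 3 measured Y-linked genes lay above the filter. A list of kidney genes written after the values were seen, with 16 measured members, was 1.34 lower by its median in the tumour of experiment 1 and 1.28 lower in experiment 2, since both healthy PBS arrays carried it (Kap 9.61 and 9.32 log2 against 5.97 and 6.07).

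By limma with Benjamini-Hochberg adjustment, 3428 genes rose and 3424 fell, 6852 in all. The smallest adjusted p was 0.0024, shared by Top2a, Mki67, S100a8 and Upk2, and among the genes said above to have risen or fallen the largest was 0.0295, for Cd3e. Without the experiment block 3172 genes passed, and Acta2 (adjusted p = 0.0884), Cd3e (0.527) and the sterol list (0.152) were no longer called. Computed within each experiment, the differences correlated at 0.965 across genes, which are not independent replicates. The camera list test called 12 lists up and 5 down, from the cell cycle list (adjusted p = 3.48e-10; 0.557 with an estimated correlation) to sterol synthesis (adjusted p = 0.0464; 0.557 with an estimated correlation). The preset p-values rest on the spread between genes, not between bladders. No list passed with an estimated correlation. That test had 1 residual degree of freedom and could hardly call any list. Even the cell cycle list, with 24 of 24 members up, had unadjusted p = 0.33 by it.

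**Figure D1:**
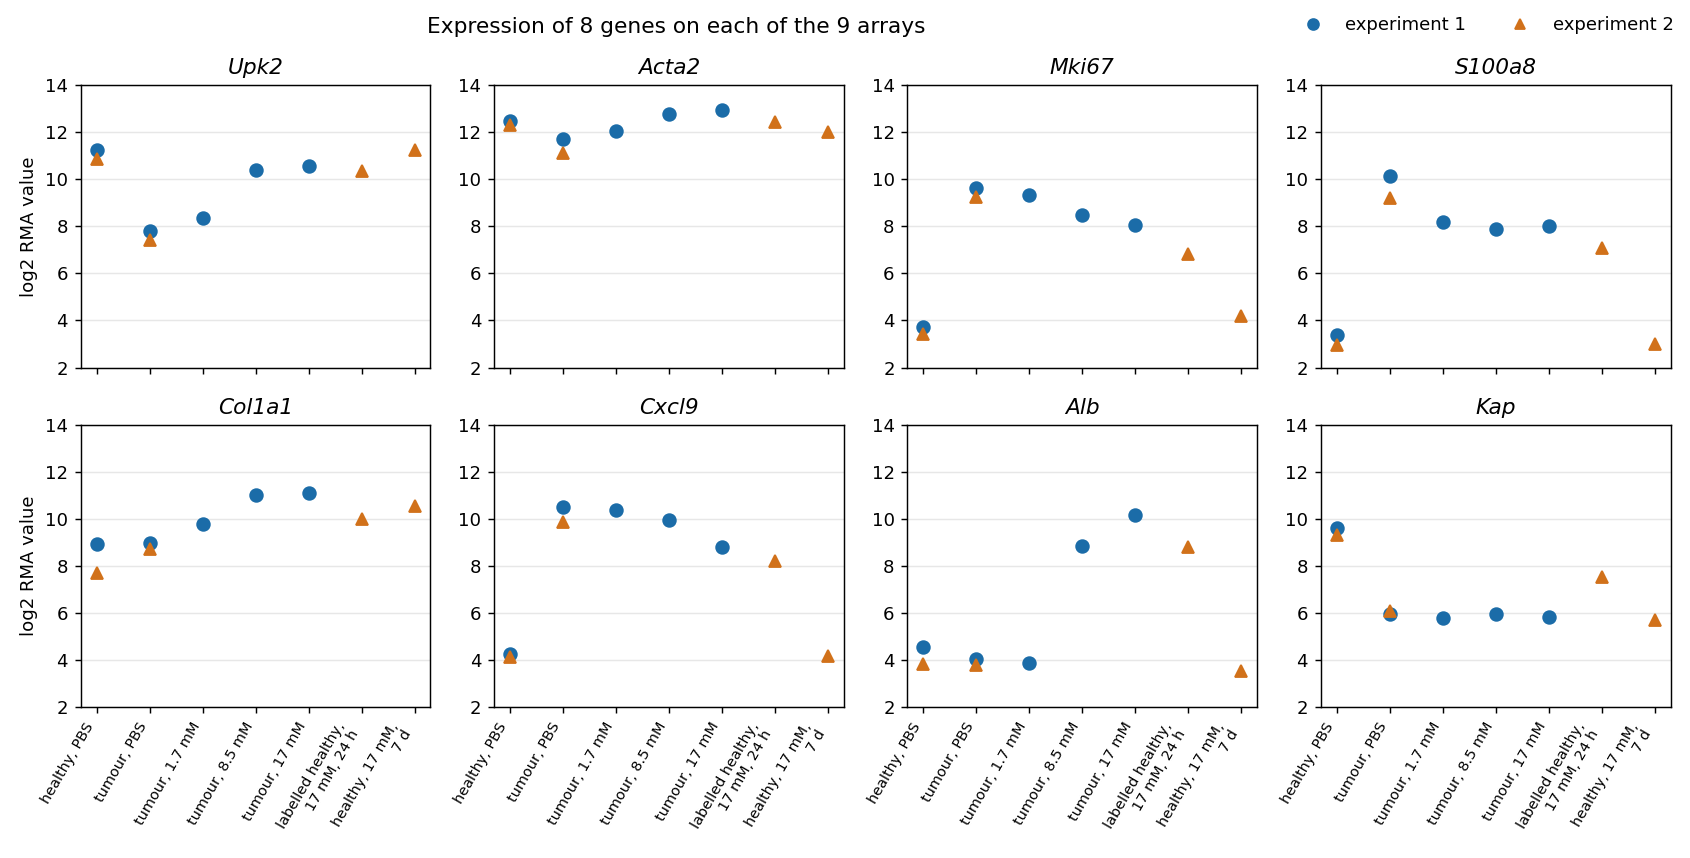
Log2 RMA value (y) of 8 genes on each array, by group (x), with circles for experiment 1 and triangles for experiment 2. Upk2 read 11.22 in healthy, 7.80 in sham-treated tumour and 10.56 in 17 mM tumour bladder of experiment 1, and Mki67 read 3.72, 9.64 and 8.05.

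In tumour bladders that had received 17 mM alpha1-oleate (1 array against 2 sham-treated tumours), urothelial and muscle transcripts were higher, and proliferation, neutrophil and interferon transcripts lower, than in sham-treated tumours. Pcp4 rose by 6.43 (log2 difference, SE 0.64, adjusted p = 0.0198), Acaa1b by 4.53 (SE 0.51, adjusted p = 0.0219) and Inmt, a methyltransferase, by 4.47 (SE 0.15, adjusted p = 0.0159). Upk2 rose by 2.76 (SE 0.12), Krt20, a keratin of umbrella cells, by 3.17 (SE 0.22), and Cldn8 by 3.97 (SE 0.27), each with adjusted p = 0.0159. Lcn2, an iron-scavenging protein of inflamed epithelium and neutrophils, fell by 4.03 (SE 0.21, adjusted p = 0.0159). Of the granzymes, proteases of cytotoxic cells, Gzmd fell by 3.67 (SE 0.48, adjusted p = 0.0265), Gzmg fell by 3.48 (SE 0.57, adjusted p = 0.0365) and Gzme fell by 2.81. The liver proteins Alb (6.00, SE 0.21) and Serpina1c (4.43, SE 0.12) rose as well. A liver list written after the values were seen, 18 measured genes of which 1 exceeded 6 log2 in control bladders, was 2.26 higher by its median in the 17 mM array, beside the urothelial, muscle and collagen genes. It was 1.32 higher in the 8.5 mM array and read -0.06 in the 1.7 mM array.

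Of the urothelial list 17 of 20 rose (17 adjusted over the list alone, median 2.54), including Upk3b (3.22) and Pparg (3.08). All 16 smooth muscle genes rose (16, median 2.73), including Pgm5 (3.48), Lmod1 (3.11), Casq2 (2.91) and Acta2 (1.34, SE 0.19, adjusted p = 0.0302). Of the basal list 5 of 15 rose and 3 fell (6 and 3 adjusted over the list alone), with Trp63 at 3.16 and Krt5 at 2.29 (SE 0.35). Of the fibroblast and collagen list 14 of 18 rose (15, median 1.06), with the small proteoglycans Lum (2.78) and Dcn (1.91), Dpt (2.73) and Col1a1 (1.88, SE 0.37, adjusted p = 0.0487). Of the endothelial list 6 of 15 rose (8), with Tek (1.56) and Sox17 (1.53). Adipose genes rose in 3 of 5 cases (3), with Plin4 at 2.76. Fatty acid oxidation genes had 8 of 16 up and 1 down (9 and 1), with Pdk4 at 3.41, and striated muscle genes 5 of 8 up and 1 down (5 and 1), with Ckm at 3.55. Xist rose by 1.08 (SE 0.12, adjusted p = 0.0215).

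Of the cell cycle genes 17 of 24 fell (20 adjusted over the list alone, median -1.57), with the mitotic motor Cenpe at -1.97 (SE 0.18), Prc1 at -1.74 and Mki67 at -1.57 (SE 0.12, adjusted p = 0.0161). Of the DNA replication genes 19 of 24 fell (24, median -1.27), with Tk1 at -1.90 and Cdc45 at -1.73. Of the neutrophil list 5 of 11 fell (6, median -1.28), with S100a8 and S100a9 both at -2.0 and the receptor Csf3r at -1.23. Of the cytokines 4 of 15 fell (6), with Cxcl1 at -2.11, Cxcl2 at -2.06 and Csf3 at -1.61, while Il1b read -1.33 (SE 0.55, adjusted p = 0.168). Of the interferon list 11 of 19 fell (14), with the antiviral Rsad2 at -1.96, Cxcl9 at -1.56 and the immunoproteasome subunit Psmb8 at -1.38. Hypoxia genes fell in 11 of 20 cases (17), led by Car9 at -2.27 and Adm at -1.82. RAS-ERK genes fell in 6 of 15 with 1 up (9 and 1), with Fosl1 at -1.91. Heat shock and unfolded protein response genes fell in 7 of 20 with 1 up (13 and 2), with Trib3 at -1.94 and Asns at -1.63.

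Of the macrophage list 1 of 17 rose and 2 fell (1 and 1 adjusted over the list alone, median -0.26). Its Cd163, a haemoglobin scavenger receptor, rose by 1.82 (SE 0.22, adjusted p = 0.0239), and Arg1 fell by 1.59. Of the T and NK list 2 of 12 fell (1 adjusted over the list alone), Cd3g by 1.0 and Cd8b1 by 0.85, while Cd3e read -0.41 (SE 0.13, adjusted p = 0.11). Of the dendritic list 1 of 11 rose and 2 fell (1 and 2). Of the proteases 2 of 13 rose and 5 fell (2 and 5), with Mmp2 at 2.26 and Mmp13 at -2.04. The p53 list had 3 up and 1 down of 14 (3 and 4), with a median of -0.28 and a mean of 0.14. There Perp rose by 3.00 and the cell cycle inhibitor Cdkn1a fell by 0.90. Growth factor receptors had 3 up and 4 down of 16 (6 and 5), EMT genes 3 up and 1 down of 12 (4 and 3), and sterol genes 3 up and 1 down of 15 (3 and 2). Mast cell genes had 1 up of 6 (4), nerve genes 2 up of 4 (3) and erythroid genes 1 down of 4 (3), the haem synthesis gene Alas2 (-2.65).

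By limma 1875 genes rose and 1272 fell at 17 mM, 3147 in all, with a smallest adjusted p of 0.0159. Without the experiment block 1096 rose and 121 fell. Genes named above that did not pass without it were Acta2 (adjusted p = 0.0501), Cenpe (0.0596), Mki67 (0.0845), Mmp13 (0.0845), Cxcl9 (0.0954), Prc1 (0.0995), Cdc45 (0.104), Arg1 (0.121), Asns (0.133), Xist (0.21), Csf3 (0.304), Cdkn1a (0.416), Psmb8 (0.422), Csf3r (0.79), Cd8b1 (0.845) and Cd3g (0.911). With all arrays quantile-normalized together, 2136 rose and 2442 fell, so the excess of increases depends on the scaling. The camera test called 6 lists up and 10 down, from DNA replication (adjusted p = 5.01e-09; 0.622 with an estimated correlation) to erythroid genes (adjusted p = 0.0326; 0.655 with an estimated correlation). No list passed with an estimated correlation.

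At 8.5 mM (1 array against 2) Pcp4 rose by 6.16, Alb by 4.68, Upk2 by 2.60 (SE 0.12, adjusted p = 0.0253) and Cpa3, a mast cell protease, by 2.02. Lcn2 fell by 4.30 and S100a8 fell by 2.11. Of the urothelial list 17 of 20 rose (17 adjusted over the list alone, median 2.36), of smooth muscle 13 of 16 (16, median 2.30) and of collagen 10 of 18 (16, median 1.10). By contrast, 8 of 24 cell cycle genes (18, median -1.11) and 16 of 24 replication genes (19, median -0.91) fell. In all 1315 genes rose and 557 fell, and without the block 904 rose and 41 fell. At 1.7 mM limma called 0 genes (1595 at unadjusted p under 0.05, smallest adjusted p 0.251, and 36 adjusted without the block). There Upk2 read 0.53, Mki67 -0.30, S100a8 -1.84, Cd163 2.02 and the lymphatic receptor Lyve1 2.65. List medians at that dose included -1.54 in erythroid, -0.375 in neutrophil, -0.371 in hypoxia and 0.45 in endothelial genes, while the cell cycle list read -0.0025. Adjusted over the list alone, 13 of 20 urothelial genes (median 0.82) and 10 of 16 smooth muscle genes (median 0.71) rose.

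**Figure D2:**
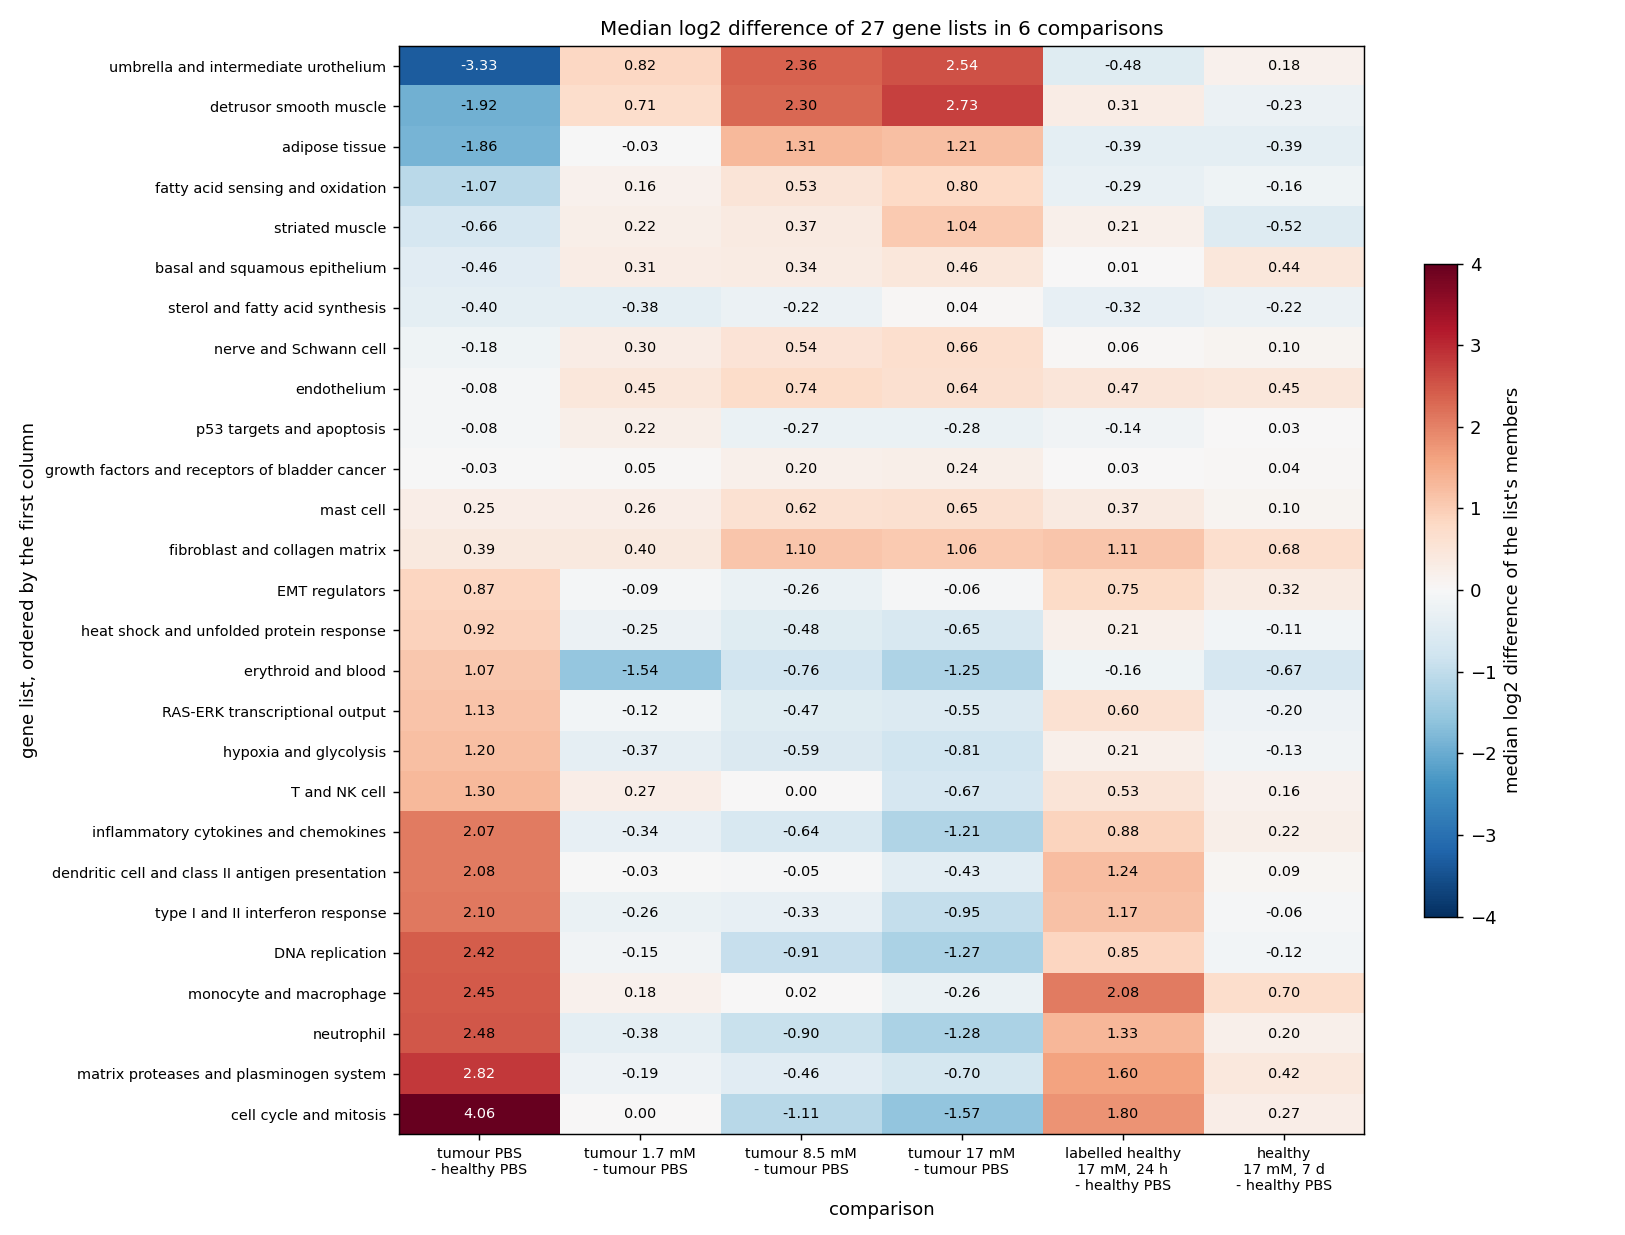
Median log2 difference (colour and printed value) of 27 gene lists (vertical) in 6 comparisons (horizontal). The urothelial list read -3.33 in tumour against healthy bladder and 2.54 in 17 mM against sham-treated tumours, and the cell cycle list read 4.06 and -1.57.

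With the 3 doses taken as one treated arm (3 arrays against 2), the mean difference from sham-treated tumours was 5.59 for Pcp4 (SE 0.92, adjusted p = 0.246), 1.97 for Upk2, 2.60 for Pgm5 and 2.41 for Lum. It was -1.98 for S100a8 (SE 0.18, adjusted p = 0.232), -2.06 for Alas2, -1.0 for Mki67 and -1.68 for Cxcl1. List medians were 1.94 in smooth muscle (4 rose adjusted over the list alone), 1.90 in urothelium (4 rose), 0.86 in collagen (2 rose), and 0.53 in endothelium (8 rose). They were -0.73 in neutrophil genes (4 fell) and -0.61 in hypoxia genes (2 fell), and no member passed over all genes. Limma called 0 genes here (2317 at unadjusted p under 0.05, smallest adjusted p 0.232, and 4 adjusted without the block, Pcp4 among them), but 2328 with the 7 groups as separate means and 5140 without the 1.7 mM array, and the arm mixes 3 doses. Camera called 6 lists up and 8 down, with hypoxia at adjusted p = 4.27e-08 (0.542 with an estimated correlation) and smooth muscle and urothelium at 1.98e-07 (0.542 with an estimated correlation).

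Across the dose series (sham-treated tumours at 0 mM, then 1.7, 8.5 and 17 mM, 5 arrays), the slope was 0.40 log2 per mM for Alb (SE 0.06, adjusted p = 0.0591), 0.29 for Pcp4, 0.23 for Cldn8 and 0.17 for Upk2. It was -0.27 for Lcn2, -0.25 for Gzmd, -0.24 for Gzmg and -0.09 for Mki67 (SE 0.01, adjusted p = 0.0591). The block fitted the single experiment 2 array here, a sham-treated tumour, exactly, so the slopes rest on the tumour arrays of experiment 1 alone. The cell cycle list had a median slope of -0.105 (24 of 24 fell adjusted over the list alone), DNA replication -0.0811 (24 of 24), smooth muscle 0.137 (15 of 16 rose), urothelium 0.138 (18 of 20 rose), and collagen 0.0609 (15 of 18 rose). The interferon list had -0.0497 (11 of 19 fell), T and NK genes -0.0527 (9 of 12 fell) and dendritic and class II genes -0.0232 (1 rose and 5 fell of 11). Interferon and T and NK genes changed most between the single 8.5 and 17 mM arrays (medians -0.70 and -0.69). Against sham the T and NK median was 0.27 at 1.7 mM and -0.67 at 17 mM, so its fall was not graded. No gene passed over all genes by limma (0, with 4880 at unadjusted p under 0.05, a smallest adjusted p of 0.0591, and 891 adjusted without the block). The count depended on how dose was coded, on the scaling of the arrays and on whether the 8.5 or 17 mM array was kept. Camera called 6 lists up and 11 down, among them cell cycle (adjusted p = 2e-11; 0.534 with an estimated correlation) and dendritic genes (adjusted p = 0.0201; 0.552 with an estimated correlation; 0.0769 without the block).

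Of 3493 genes that differed at least 2-fold between tumour and healthy bladder in experiment 2, 1684 were higher in the tumour and 1809 lower. In experiment 1, whose arrays did not choose these genes, the 17 mM tumour differed from sham in the opposite direction in 98.2% of them, the 8.5 mM tumour in 97.0% and the 1.7 mM tumour in 83.2%. The median share of the tumour difference that was undone was 62.1%, 50.7% and 14.7% at 17, 8.5 and 1.7 mM. Tumour-low genes had a median of 1.34 at 17 mM and tumour-high genes -0.93. By linear signal, 594 genes high in tumour kept a median of 28.3% of their tumour excess at 17 mM. Among them the 6 neutrophil genes kept 23.9%, the 23 cell cycle genes 29.0%, the 10 interferon genes 28.7% and the 7 cytokine genes 26.8%. The 12 macrophage genes kept 69.0% and the 5 class II genes 44.5%. The collagen list did not stop at the healthy value: all 18 members at 17 mM lay above both the sham-treated tumour and the healthy bladder of the same experiment, by a median of 0.94. So did all 16 smooth muscle genes, by 0.70, and 13 of 15 endothelial genes, by 0.36. The correlation across genes of the 2 differences was -0.868 at 17 mM, -0.833 at 8.5 mM and -0.554 at 1.7 mM, and genes are not independent replicates.

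**Figure D3:**
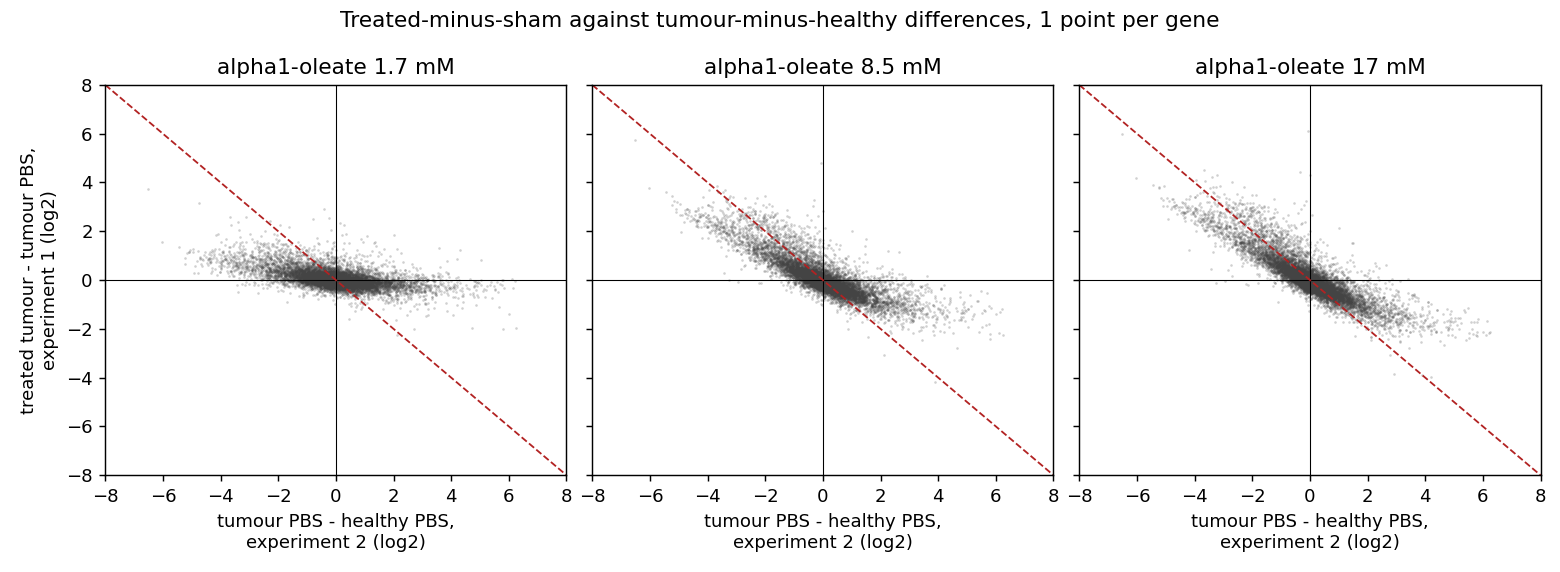
Each point is 1 gene, with tumour PBS minus healthy PBS in experiment 2 (x, log2) against treated minus sham-treated tumour in experiment 1 (y, log2), and the dashed line marks full reversal. The cloud steepens from 1.7 mM (correlation across genes -0.554) to 17 mM (-0.868).

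The array labelled healthy, 17 mM, 24 h read far above the healthy PBS arrays (1 array against 2) for many genes that were high in the tumours. S100a8 was 4.23 higher, the attractant Cxcl9 4.18 (SE 0.23, adjusted p = 0.0577), Birc5 4.04, Top2a 3.93, Mki67 3.44 (SE 0.12, adjusted p = 0.0568), Rrm2 3.48, Mmp13 3.69 and Krt14 3.68. Ccl2 was 3.59 higher, Cxcl10 3.54, Timp1, an inhibitor of metalloproteases, 3.24 and Arg1 2.73. Col1a1 was 2.06 higher (SE 0.37, adjusted p = 0.145), Il1b 2.46 and the S100 protein S100a4 2.85, while Upk2 read -0.50, Acta2 0.24 and Xist -0.14. Alb was 4.84 higher (SE 0.21, adjusted p = 0.0568) and the later-written liver list 1.65 higher by its median, beside the proliferation, macrophage and collagen genes. Among the 5 lowest values were those of the kidney genes Miox (-1.98), Kap, an androgen-regulated kidney protein (-1.89), and Keg1 (-1.68), and the kidney list read -0.99. Both healthy PBS arrays carried these kidney transcripts. In experiment 2 Kap read 9.32 in healthy PBS, 7.53 in this array and 6.07 in the sham-treated tumour.

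The cell cycle list had a median of 1.80 in that array (22 of 24 rose adjusted over the list alone), the macrophage list 2.08 (16 of 17), the protease list 1.60 (11 of 13) and the neutrophil list 1.33 (5 of 11). The dendritic and class II list had 1.24 (9 of 11), the interferon list 1.17 (15 of 19), the collagen list 1.11 (14 of 18), the DNA replication list 0.85 (18 of 24) and the EMT list 0.75 (6 of 12). Urothelial genes had a median of -0.48 with 0 called adjusted over the list alone, smooth muscle 0.31 and basal genes 0.01. Over all genes limma called 0 (2503 at unadjusted p under 0.05, smallest adjusted p 0.0568), and without the experiment block it called 122 genes higher and 4 lower, with Alb, S100a8, Cxcl9, Birc5, Top2a and Mki67 among the 122. Camera called 15 lists up and 3 down, led by the cell cycle list (adjusted p = 2.29e-16; 0.512 with an estimated correlation) and the macrophage list (adjusted p = 8.92e-15; 0.512 with an estimated correlation). The list p-values rest on the spread between genes, not between bladders. Across genes, the difference of this array from healthy PBS in experiment 2 correlated at 0.912 with that of the 17 mM tumour in experiment 1 and at 0.727 with that of the sham-treated tumour in experiment 1, and genes are not independent replicates.

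Healthy bladder 7 d after 17 mM (1 array against 2) read closer to the controls for Mki67 (0.80), S100a8 (0.16) and Upk2 (0.37) than the 24 h array did. Among the largest positive values were those of Dkk2, a secreted WNT regulator (2.83, SE 0.14, adjusted p = 0.403), Col1a1 (2.61, SE 0.37, adjusted p = 0.488), Akap9 (2.47), the membrane metalloprotease Mmp14 (2.19) and the collagen cross-linking enzyme Lox (1.95), with the macrophage genes Ms4a7 at 1.72 and Adgre1 at 1.39. The 5 lowest values were those of Kap (-3.70, SE 0.18), Erdr1 (-3.62), the fatty acid transporter Slc27a2 (-3.15), Miox (-3.11) and the clock-controlled factor Dbp (-2.72). The later-written kidney list, which holds Kap, Slc27a2 and Miox, read -1.05. Again the healthy PBS arrays were the ones that carried kidney transcripts. In experiment 2 Kap read 9.32 in healthy PBS, 5.72 at 7 d and 6.07 in the sham-treated tumour. By list, collagen genes had a median of 0.68 (10 of 18 rose adjusted over the list alone), macrophage genes 0.70 (8 of 17 rose), endothelial genes 0.45 (5 of 15 rose) and basal genes 0.44 (1 of 15 rose). Striated muscle had -0.52 (2 of 8 fell), adipose -0.39 (2 of 5 fell) and smooth muscle -0.23 (3 of 16 fell). Limma called 0 genes over all genes (1096 at unadjusted p under 0.05, smallest adjusted p 0.403, and 15 adjusted without the block, among them Dkk2, Col1a1, Kap, Erdr1, Slc27a2, Miox and Dbp). Camera called 10 lists up and 6 down, with collagen, endothelium and macrophages each at adjusted p = 7.57e-09 (0.718 with an estimated correlation).

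The difference between the 17 mM effect in tumours and the mean 17 mM effect in healthy bladder passed for 1928 genes. Of the 94 passing genes named by the fixed rule, 23 still passed with the 7 d array alone and 71 did not. Those named here that did were Mki67, Top2a, Dbp, Pdk4, Ckm, Pgm5 and Upk2. S100a8 read -2.0 in tumours, 4.23 in the array labelled healthy, 17 mM, 24 h and 0.16 at 7 d, a difference of -4.20 (SE 0.32, adjusted p = 0.0305). Mki67 differed by -3.69 (SE 0.17), Birc5 by -3.91, Top2a by -3.76, Mmp13 by -3.96, Cxcl9 by -3.73, Arg1 by -3.14 and the hexokinase Hk2 by -2.49. Mki67 read 3.72 and 3.41 in the healthy PBS arrays, below the filter level of 4.16, so it could hardly fall there. The number of instillations and the sampling times also differed between tumour and healthy mice. This contrast therefore cannot tell the tissue setting from the schedule. Healthy bladder also had no tumour-related decrease that treatment could undo. The urothelial list rose by a median of 2.54 at 17 mM in tumours and read -0.48 at 24 h and 0.18 at 7 d. Its positive values in the contrast thus mostly restate the difference from sham-treated tumours. In the positive direction were Pcp4 (6.29, SE 0.91, adjusted p = 0.0419), Dbp (5.01, SE 0.22, adjusted p = 0.0305), Acaa1b (4.73), Pdk4 (4.13), Cldn8 (4.07), Upk3b (3.60), Ckm (3.56), Pgm5 (3.48) and Upk2 (2.83). Col1a1, higher in both settings, read -0.46 (adjusted p = 0.581), Acta2 1.31 (adjusted p = 0.0654) and Krt5 2.09 (adjusted p = 0.0807).

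Of the cell cycle list 17 of 24 genes had a lower effect in tumours (22 adjusted over the list alone, median -2.66), of DNA replication 16 of 24 (24), of the interferon list 12 of 19 (16), of macrophage genes 9 of 17 (13), and of hypoxia genes 7 of 20 (11). The same held for 6 of 15 cytokines (8) and 5 of 11 neutrophil genes (8, median -2.14). Of the urothelial list 14 of 20 had a higher effect (17, median 2.66), of smooth muscle 10 of 16 (16, median 2.51) and of adipose genes 4 of 5 (4). Collagen genes had 2 of 18 higher (0 adjusted over the list alone) and a median of 0.01. With the 7 d array alone, a choice added after the values were seen, 2 of 24 cell cycle genes had a lower effect in tumours (17 adjusted over the list alone), 1 of 24 replication genes (16), 1 of 19 interferon genes (11), 2 of 20 hypoxia genes (6), and 0 of the macrophage (9), cytokine (5) and neutrophil (6) lists by limma. A higher effect was then called for 3 of 20 urothelial (17), 6 of 16 smooth muscle (16) and 2 of 5 adipose genes (4). By limma 1202 genes had a higher and 726 a lower effect in tumours, 1928 in all with a smallest adjusted p of 0.0305. Without the block it called 1068 and 170, and Krt5 then passed as well. Of the 2 treated healthy arrays in this contrast 1 is the array labelled healthy, 17 mM, 24 h, and with the 7 d array alone 330 were higher and 53 lower. Camera called 4 lists up and 12 down, with cell cycle at adjusted p = 7.37e-11 (0.583 with an estimated correlation) and urothelium at 9.14e-09 (0.583 with an estimated correlation).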

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

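The tests of explanations in this part, and the genes and arrays they use, were chosen after the results were seen, while the contrast of 17 mM effects was planned.

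The array labelled healthy, 17 mM, 24 h carried transcripts that the other tumour-free bladders did not, such as Ott, Xlr and Dppa2, which read 5.65, 4.83 and 5.08 there and 2.58, 2.53 and 2.72 in healthy PBS of the same experiment. In a response of tumour-free tissue, genes nearly silent in healthy bladder and outside the fixed lists would stay low. The 25 such genes at least 16-fold above healthy in the sham-treated tumour of experiment 1 had a median of 2.08 in this array against healthy PBS. That median cannot decide the question, because a tissue response could raise some of the 25. Cdkn3 and Ncapg belong to proliferation, and Gzmd, Gzmg and Ccr1 to leukocytes. Ott, Xlr and Dppa2, also among the 25, were picked for the germline list after these values were seen, so they cannot decide the question either. The array may instead hold material of a treated tumour bladder. Its difference from healthy PBS correlated across genes at 0.912 with that of the 17 mM tumour of the other experiment and at 0.727 with that of the sham-treated tumour. The liver list stood 1.65 higher, as in the 8.5 and 17 mM tumours. This array and the 17 mM tumour both received 17 mM by their labels. A shared response to the compound could therefore also give the closer correlation, which does not separate these explanations. A plain exchange with the 17 mM tumour array is less likely, because the same 25 genes read 3.45 above healthy there. By linear signal, 690 tumour-high genes stood at a median of 21.7% of the tumour excess in this array, and at 0.48% at 7 d. The 23 cell cycle genes stood at 20.2%, so they showed no excess over tumour-high genes as a whole. The 9 cytokine genes stood at 26.3%, the 10 interferon genes at 29.7%, the 6 class II genes at 45.7% and the 12 macrophage genes at 58.35%. Whether a tissue response adds to the proliferation and inflammation genes of this array was not tested beyond these shares.

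The 17 mM tumour array lay nearer to healthy bladder than the sham-treated tumours did. Liver RNA in the sample could not give this, since the urothelial list rose by a median of 2.54. A smaller share of tumour in the bladder may account for part of it. Of their excess, all 594 tumour-high genes kept 28.3%, the 23 cell cycle genes among them 29.0%, the 10 interferon genes 28.7% and the 7 cytokine genes 26.8%. Against an even loss, the 12 macrophage genes kept 69.0% (quartiles 51.7 and 85.9). The 5 class II genes kept 44.5%, but their quartiles (31.9 and 45.0) overlapped those of all tumour-high genes (21.1 and 37.9). A smaller share of tumour is unlikely to be the whole cause, because the collagen list lay 0.94 above the higher of sham-treated tumour and healthy bladder. How far the treatment lowered tumour mass, and how far it changed the tissue around it, stays open and was not tested.

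The contrast of the 17 mM effect in tumours with that in healthy bladder passed for 1928 genes, and 1 of its 2 treated healthy arrays is the array labelled healthy, 17 mM, 24 h. Its largest positive values were Pcp4 6.29, Dbp 5.01, Acaa1b 4.73, Npy6r 4.65 and Inmt 4.64, and its largest negative ones Gzmd -4.41, AA467197 -4.34, S100a8 -4.20, Bcl2a1a -4.08 and Lcn2 -4.07. With the 7 d array alone Dbp, Npy6r, Inmt, Bcl2a1a and Lcn2 still passed and the other 5 did not. Bcl2a1a read 4.47 and S100a8 4.23 in the array labelled healthy, 17 mM, 24 h against healthy PBS, whereas Pcp4, Gzmd and Lcn2 read 6.43, -3.67 and -4.03 in the 17 mM tumour against sham, and the cause was not tested.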

How the results depend on the processing

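Without the experiment block, that is without pairing the arrays of an experiment, the count of genes passing was 3172 for tumour against healthy, 4 for the treated arm, 1217 for 17 mM, 891 for the dose slope, 126 for the 24 h array, 15 for 7 d and 1238 for the contrast of 17 mM effects. In the blocked fit these were 6852, 0, 3147, 0, 0, 0 and 1928. Of the genes named by the fixed rule, calls lost without the block numbered 10 of 112 in tumours, 47 of 108 at 17 mM and 31 of 94 in the contrast, and calls gained 2 in the treated arm, 25 for the 24 h array, 7 for 7 d and 3 in the contrast. Of the lists called by camera, those lost were sterol synthesis in tumours, dendritic genes in the dose slope, hypoxia and fatty acid oxidation in the 24 h array, and heat shock, cytokines, neutrophils and urothelium at 7 d. Those gained were proteases and RAS-ERK in the treated arm, basal, protease and striated muscle genes at 17 mM, erythroid genes in the dose slope, basal genes in the 24 h array, and erythroid and striated muscle genes in the contrast. The unblocked fit changed no other call of a named gene or list in these comparisons, except that genes of the dose slope were compared by count alone.

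With a 2-fold requirement 3482 genes passed in tumours and 1954 at 17 mM. With the 7 groups as separate means 2328 passed for the treated arm. Quantile normalization of all arrays together gave 1455 for the dose slope, 833 for the 24 h array, 7 for 7 d and 3449 for the contrast of 17 mM effects. Dose as log2 of dose plus 1 gave 4984 genes and dose as a rank 4200. For the 24 h array, a filter at the 50th percentile gave 121, the mean of probe sets 96 and a variance trend 198. For the contrast, no filter gave 1275 and the 7 d array alone 383.

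Of the lists that camera called at its preset correlation, 0 passed with an estimated correlation in all 7 planned comparisons. With 1 to 3 residual degrees of freedom that test could hardly call any list, so it cannot tell whether a list changed. With fry 0 passed for the treated arm, 17 mM, the dose slope, 7 d and the contrast, and 1 for the 24 h array, the EMT list. For tumour against healthy fry also called 17 lists, 14 of them shared with camera: it did not call cytokines (adjusted p = 0.1), neutrophil (0.0977) or T and NK genes (0.104), and it called EMT, nerve and striated muscle genes (0.0439 each). The share of reversed genes under 3 other choices was 78.51, 88.07 and 79.43% at 1.7 mM and 95.03, 97.91 and 95.91% at 8.5 mM, and under 2 of them 96.63 and 98.68% at 17 mM.

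Arrays were left out one at a time, with a lone array of a group assumed to vary like the replicated ones. Leaving out the 24 h array could not change the blocked counts for tumour against healthy, 17 mM, the treated arm, the dose slope and 7 d. That array is alone in its group and enters none of these contrasts, so its removal tests nothing there. Removing the sham-treated tumour of experiment 2 likewise tests nothing for the blocked dose slope, where the block fits it exactly. In blocked fits without a tumour array (or, for the treated arm, a healthy PBS array), the treated arm gave 5140 without the 1.7 mM array and otherwise 0, and the dose slope 1839 without the 8.5 mM array, 1384 without the 17 mM array and otherwise 0. For the other comparisons a blocked fit without a PBS array has no residual degree of freedom and was not possible, so these were left out without the block, an alternative added after the data were seen, and are to be set against the unblocked counts above. Counts then ran from 2230 to 2807 for tumour against healthy, 850 to 1378 for 17 mM, 76 to 153 for the 24 h array, 7 to 21 for 7 d and 639 to 1597 for the contrast. They moved by over 1.5 times without the healthy PBS array of experiment 2 for the 24 h array (76), and without that of experiment 1 for 7 d (7) and the contrast (639). At 17 mM, Csf3r and Cd3g read -1.23 and -1.0 with the block and -0.58 and -0.44 without it. Leaving out the sham-treated tumour of experiment 1 as well, where the contrast crosses experiments, turned them to 0.18 and 0.21, and leaving out that of experiment 2 gave -1.35 and -1.10, and the cause was not tested. A fit with only the arrays of the compared groups had no residual degree of freedom for 17 mM, 24 h and 7 d and was not run.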

Other observations

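The genes in this part were picked after the values were seen. Their values are given per array, without a test. In experiment 1, the clock-controlled gene Dbp read 8.62 in healthy bladder, 4.63 in sham-treated tumour, and 5.98, 6.75 and 8.24 at 1.7, 8.5 and 17 mM, and Nr1d2, a clock repressor, read 10.17, 8.12, 9.24, 9.39 and 10.11. Arntl, the activator of the opposite phase, read 5.04, 7.26, 6.92, 6.42 and 5.86. In experiment 2, Dbp read 8.04 in healthy bladder, 4.32 in sham-treated tumour, 7.89 in the array labelled healthy, 17 mM, 24 h and 5.39 at 7 d. From sham through 1.7, 8.5 and 17 mM in experiment 1, Cd274, which encodes PD-L1, read 7.88, 7.66, 7.06 and 6.27, and Ido1, a tryptophan-degrading enzyme, read 6.94, 6.72, 5.54 and 4.93.

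Dkk2 read 4.59 in healthy and 4.88 in sham-treated tumour bladder of experiment 1 and 7.00 and 7.54 at 8.5 and 17 mM, and it read 3.62 in healthy bladder of experiment 2, 6.80 in the array labelled healthy, 17 mM, 24 h and 6.40 at 7 d. A list of 14 glucocorticoid-response genes, 13 of them measured, 12 also above 6 log2 in control bladder and 2 in the fixed lists, had a median of 1.50 at 1.7 mM against sham, with 8 above 1, and of -0.41 and -0.06 at 8.5 and 17 mM. Tsc22d3, an anti-inflammatory target of the receptor, read 10.99 at 1.7 mM and 8.75 in sham. The genes of the later-written germline list, Ott, Xlr and Dppa2, were 5.91 higher by their median in the tumour of experiment 1 and 5.43 in experiment 2, 2.34 lower at 17 mM than in sham, and 2.36 higher in the array labelled healthy, 17 mM, 24 h. The kidney list, with 7 of its 16 measured members above 6 log2 in control bladders, and the liver list, of which 0 are in the fixed lists, were the only lists of other organs examined.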
